A study of Rattus norvegicus with 15 samples.

How the data were processed

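The deposited data are 15 droplet libraries of rat lung cells made with the 10x Genomics 3' kit: dissociated whole lung (PD), lavage (BAL) and 3 kinds of organoid (PD_3D, Mixed_3D, BAL_3D), 3 libraries each. Per the labels, the authors aligned reads to the rat build Rnor_6.0 with Cell Ranger 8.0.1 and used Seurat, whose version is not given. Per the file headers, 3 libraries were made with Cell Ranger 7.1.0 and 12 with 8.0.1. The deposited matrices hold raw counts, unfiltered UMI counts for 32883 genes in all barcodes, and the values are whole numbers. The deposited barcode and gene lists that name the columns and rows of each matrix are in another unit (other), since they hold names and no measurement. Genes are named by the symbols the gene lists give, and list members were matched to those symbols exactly.

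Barcodes with at least 1000 UMIs, at least 500 genes and at most 20% mitochondrial UMIs were kept. Of PD barcodes with that many UMIs and genes, 2013 of 5238, 2778 of 7745 and 1581 of 7301 were over the mitochondrial limit. Doublets were scored per library against simulated doublets, and a share of 0.8% per 1000 cells was removed. Counts were scaled to 10000 per cell and logged, and cells were clustered on 2000 variable genes, 30 components and 20 neighbours by the Leiden method at resolution 1, which gave 44 clusters. Clusters were named by marker lists fixed in advance, where at least 3 markers stood out. Epithelial cells were clustered again into 34 subclusters and named likewise. After the data had been seen, a rule was added that leaves a subcluster unnamed where over 50% of its cells came from a low-UMI cluster (median under 2000 UMIs) led by club and ciliated genes. The empty-barcode profile was summed over barcodes with at most 100 UMIs.

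For each class, UMIs were summed per library, and libraries with fewer than 20 cells of the class were left out of that class. Genes were tested with edgeR (quasi-likelihood test after filterByExpr and TMM scaling) in 1 fit of all groups, and a gene passed at a Benjamini-Hochberg adjusted p of 0.05. In all 16373 genes were tested in epithelial cells and 14712 in macrophages. CPM values are TMM-scaled counts of the class sum of each library, with the SD over libraries, and fold changes are log2 with their standard error. Of 12 planned comparisons, 8 could be tested and 4 could not, since fewer than 2 libraries of a group reached 20 cells. The difference between both culture changes was tested as an interaction in the same fit. Of 37 gene lists, each with at least 3 tested members, all were tested with limma's camera at its preset correlation of 0.01, with camera at a correlation estimated per list, and with fry. Over the 8 comparisons and the interaction, camera at the preset correlation called 16 lists in PD_3D against PD, 20 in BAL_3D against BAL, 14 in BAL_3D against PD_3D, 13 in Mixed_3D against PD_3D, 21 in Mixed_3D against BAL_3D and 9 in the interaction. It called 28, 15 and 15 lists in macrophages of BAL against PD, BAL_3D against BAL and Mixed_3D against BAL_3D. With an estimated correlation none was called in epithelial cells, and 4, 1 and 2 were in macrophages. Fry, which asks whether the genes of a list move on balance one way, called 22, 19, 11, 0, 15 and 4 lists in epithelial cells and 32, 19 and 8 in macrophages.

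Shares of cells were compared between groups with 2-sided exact permutation tests, and over the organoids by the slope against the percentage of BAL cells seeded, with 1680 arrangements of the libraries. Adjusted values are over the types of 1 family of shares.

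Genes named in the report follow a rule fixed before the data were examined, like the lists, the thresholds and the comparisons: among genes past the threshold with an absolute log2 fold change of at least 1 and at least 20 CPM in the higher group, whose libraries do not overlap between the groups, the 6 largest rises and 6 largest falls. Ribosomal, mitochondrial and haemoglobin genes, markers of another class, names that are only identifiers and genes under 50% of their level in empty barcodes were passed over among these, and list members were not held to that. Not every gene that meets the rule is named. Each list described adds its 3 members with the smallest p and the 2 members with the highest CPM that did not pass. The lists described were chosen among those called by camera after the results were seen. Chance alone keeps 10% of genes from overlapping with 3 against 3 libraries. The eligible genes were 1673 in PD_3D against PD, 1638 in BAL_3D against BAL, 46 in BAL_3D against PD_3D, 44 in Mixed_3D against BAL_3D, 291 in macrophages of BAL against PD, 1069 in BAL_3D against BAL and 52 in Mixed_3D against BAL_3D. The genes named for cells too few to test were chosen after their values were seen, among the first members of lists fixed in advance.

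A gene with no count in a group was given a fold against a floor of 3 counts over that group's summed UMIs, and one with 1 to 3 counts a ratio with its 95% counting interval. Floors and intervals cover counting error only. The epithelial sums hold 66844872 UMIs in PD, 1532040 in BAL, 197424908 in PD_3D and 276694385 in BAL_3D, so a count of 0 limits a gene least in BAL.

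The tests were tested on simulated data, in which 200 genes at or above 5 CPM in real class sums were changed 2-fold or 4-fold. At 2-fold, 12% to 18% were called in epithelial comparisons and 22% to 35% in macrophages. At 4-fold, 77% to 93% and 92% to 96% were called, with 2.0% to 8.1% of calls false. The simulated libraries had no structure by replicate number, so recovery in the real ones may be lower. Pairing by replicate number was checked on 2000 variable genes as the correlation of deviations from the group mean. It held for PD_3D and PD (r = 0.551, 0.279 and 0.359) and for Mixed_3D and PD_3D (r = 0.743, 0.502 and 0.594), and not for the other comparisons. The labels state no pairing, so the unpaired test is the main one and the replicate block an alternative. The libraries were checked for duplicates, and none was found.

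Alternatives planned in advance were size factors of DESeq2 in place of TMM, no gene filter, the replicate block, at least 50 cells per library, subtraction of the empty-barcode profile at 10% of each class sum, other minimums of UMIs and genes (2000 and 1000, or 500 and 250), at most 10% mitochondrial UMIs, no doublet removal, DESeq2's own test, fits of 2 groups only, other cluster resolutions (0.5, 1.5 and 2), an estimated correlation, and leaving out each library in turn. Chosen after seeing the data were the Cell Ranger 8.0.1 libraries alone, AT2-like cells alone and the 2 groups with a replicate block. Epithelial sums without the low-UMI club or secretory cluster were chosen then as well. With DESeq2 size factors the median log2 fold change of all genes moved from 0.294 to 0.138 in epithelial BAL_3D against BAL, from -0.015 to -0.125 in BAL_3D against PD_3D, and from 0.069 to -0.072 in macrophages of BAL against PD. Signalling between cell types was not analysed here. Python 3.11.15 was used with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.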

Results

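RNA of single rat lung cells was sequenced in 15 droplet libraries that fall into 5 groups of 3. PD libraries held cells released from whole lung by enzymatic dissociation, and BAL libraries held cells washed out of the airspace by bronchoalveolar lavage. Organoids were grown for 10 days from PD cells alone (PD_3D), from BAL cells alone (BAL_3D) or from a 50:50 mix (Mixed_3D), in medium with FGF10, EGF and inhibitors of TGF-beta and GSK3 signalling. The design asks how the starting mix of immune, epithelial and mesenchymal cells shapes the cells found after culture. Total UMI counts in replicates 1, 2 and 3 were 59738593, 54629079 and 101086199 in PD, and 31039768, 171725713 and 187040530 in BAL. They were 117779295, 92812836 and 73286025 in PD_3D, 139882186, 31874358 and 105035456 in Mixed_3D, and 83908700, 132923881 and 123176172 in BAL_3D. After filtering, PD kept 3142, 4770 and 5458 cells, BAL 1468, 9589 and 9363, PD_3D 2056, 3040 and 4403, Mixed_3D 3477, 590 and 2954, and BAL_3D 2503, 3632 and 3584. Epithelial cells were shallower in the fresh libraries, with a median of 3827 UMIs in PD and 4633 in BAL against 11084 in PD_3D, 19150 in Mixed_3D and 19532 in BAL_3D. Replicate 1 of PD, PD_3D and Mixed_3D was made with Cell Ranger 7.1.0 and the other libraries with 8.0.1. Values within the 8.0.1 libraries are therefore given beside the pooled ones, and the 7.1.0 libraries are 1 per group and too few for a value of their own.

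Lavage and dissociation started the cultures from different cells. Macrophages made up 94.8% ± 4.14 of BAL cells and 22.1% ± 9.20 of PD cells (SD, n = 3 each), and epithelial cells 2.09% ± 2.15 of BAL and 42.6% ± 12.1 of PD. PD also held 13.6% ± 6.73 endothelial cells, 10.1% ± 4.40 B or plasma cells, 6.80% ± 3.53 mesenchymal cells, 3.97% ± 1.48 T or NK cells and 0.726% neutrophils. BAL held no endothelial cell, 1 mesenchymal cell, 1.94% ± 1.88 T or NK cells and 0.365% ± 0.231 B or plasma cells. The difference between BAL and PD was 72.6 percentage points for macrophages and -40.5 for epithelial cells (72.4 and -43.5 within Cell Ranger 8.0.1). Over the alternatives other than leaving out a library, the epithelial difference ran from -43.53 to -26.45. Of the 5737 PD epithelial cells, 2569 lay in 1 cluster with a median of 1762 UMIs. The difference was -13.6 for endothelial, -9.74 for B or plasma and -6.80 for mesenchymal cells (-9.87, -10.7 and -7.11 within 8.0.1). Each of these had a 2-sided exact permutation p of 0.1, the smallest that 20 arrangements of 3 against 3 libraries allow (adjusted p = 0.14). T or NK cells (-2.03 points) and neutrophils (-0.191 points) each had an exact permutation p of 0.3.

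**Figure D1:**
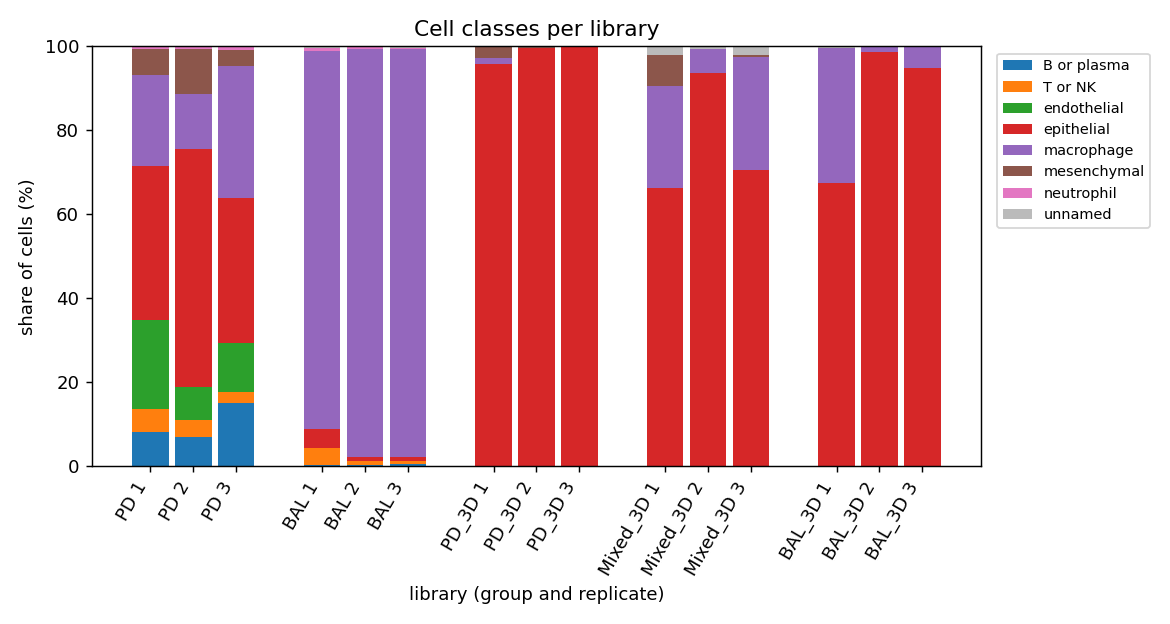
Share of cells (%) of each class in each of the 15 libraries, stacked to 100%. Macrophages average 94.8% of BAL cells, and epithelial cells average 98.4% of PD_3D, 76.7% of Mixed_3D and 86.9% of BAL_3D cells.

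Culture left mostly epithelial cells whichever suspension was seeded. Epithelial cells made up 98.4% ± 2.20 of PD_3D, 76.7% ± 14.7 of Mixed_3D and 86.9% ± 17.1 of BAL_3D cells (SD, n = 3 each). Macrophages made up 0.507% ± 0.745 of PD_3D, 19.0% ± 11.5 of Mixed_3D and 12.9% ± 16.8 of BAL_3D cells, and in BAL_3D they ranged from 1.32% to 32.2%. Mesenchymal cells made up 1.07% ± 1.36 of PD_3D and 2.64% ± 4.12 of Mixed_3D cells, and BAL_3D held 1. From PD to PD_3D the epithelial share rose by 55.8 points, and the macrophage, endothelial, B or plasma and mesenchymal shares fell by 21.6, 13.6, 10.1 and 5.73 points. Each had an exact permutation p of 0.1, the smallest possible (adjusted p = 0.1). Within 8.0.1 the epithelial, macrophage and mesenchymal differences were 54.1, -22.3 and -6.83 points, where the smallest possible exact p is 0.333. Over the alternatives other than leaving out a library, the epithelial difference ran from 51.96 to 69.88 points and the mesenchymal one from -8.705 to -4.632. From BAL to BAL_3D, all made with 8.0.1, the epithelial share rose by 84.8 points and the macrophage share fell by 81.9 points (exact permutation p = 0.1, adjusted p = 0.12).

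Across the 3 kinds of organoid, no share followed the seeded BAL percentage past the threshold. The macrophage share changed by 12.4 points per 100 points of seeded BAL (exact permutation p = 0.262, adjusted p = 0.798; 11.7 within 8.0.1) and the epithelial share by -11.4 (p = 0.319, adjusted p = 0.798; -11.4 within 8.0.1). Without BAL_3D 1 the macrophage and epithelial trends were 5.35 and -4.85 points, and without BAL_3D 2 they were 19.6 and -19.3. The mesenchymal trend was -1.06 points (exact permutation p = 0.689, adjusted p = 1; -0.293 within 8.0.1), from -1.83 without PD_3D 3 to -0.662 without PD_3D 1.

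AT2-like cells, the surfactant-making type, were the most frequent epithelial subtype in every kind of organoid, BAL_3D included. They made up 63.5% ± 21 of epithelial cells in PD_3D, 60.1% ± 14.3 in Mixed_3D and 76.1% ± 16.3 in BAL_3D, against 17.3% ± 12.1 in PD and 5.22% ± 2.23 in BAL, where they were 12 cells (SD, n = 3 each). Club or secretory cells, the airway secretory type, made up 58.8% ± 4.46 of BAL and 32.8% ± 21.7 of PD epithelial cells, against 3.42% ± 2.94 in PD_3D, 5.98% ± 7.05 in Mixed_3D and 0.418% ± 0.319 in BAL_3D. Ciliated cells made up 20.4% ± 10.9 in BAL and 7.91% ± 6.09 in PD, against 1.32% ± 1.51, 0.657% ± 0.684 and 0.205% ± 0.330 in PD_3D, Mixed_3D and BAL_3D. Basal cells were not found among the 227 BAL epithelial cells and made up 1.73% ± 2.93 in PD (59 of its 61 basal cells in PD 1), 9.19% ± 7.86 in PD_3D, 9.43% ± 7.53 in Mixed_3D and 12.9% ± 9.74 in BAL_3D. Hillock or squamous cells, a keratinising airway type, made up 11.4% ± 10.4 of PD_3D, 14.6% ± 17.3 of Mixed_3D and 7.39% ± 6.80 of BAL_3D epithelial cells and were 2 cells in BAL. AT1-like cells, the gas-exchange type, made up 7.18% ± 4.8 in PD, 3.62% ± 2.59 in PD_3D, 3.92% ± 1.88 in Mixed_3D and 0.236% ± 0.180 in BAL_3D. Per 100 points of seeded BAL the AT1-like share changed by -3.38 points (exact permutation p = 0.0798, adjusted p = 0.558; -2.24 within 8.0.1; -0.0169 with subclusters at resolution 0.5 or 1.5) and the AT2-like share by 12.7 (p = 0.389, adjusted p = 0.793; 3.03 within 8.0.1). The AT2-like trend was 3.08 without BAL_3D 1 and 23.9 without PD_3D 3. At resolutions 0.5 and 1.5 the AT1-like trend of the organoids all but vanished, and their AT1-like shares rest on the resolution used. The basal trend was 3.66 points (2.72 within 8.0.1, 8.83 at resolution 1.5) and turned to -0.678 without BAL_3D 2 (8.22 without BAL_3D 1). The hillock trend was -3.96 points and turned to 1.36 within 8.0.1 (-9.14 at resolution 1.5, -9.65 without PD_3D 3, -0.101 without PD_3D 1), and the club trend was -3.00 (-4.43 within 8.0.1, -0.412 at resolution 0.5); their exact permutation p-values over all libraries were 0.567, 0.711 and 0.459. Cells left without a subtype made up 29.2% ± 40.2 of PD epithelial cells, most of them in PD 2.

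**Figure D2:**
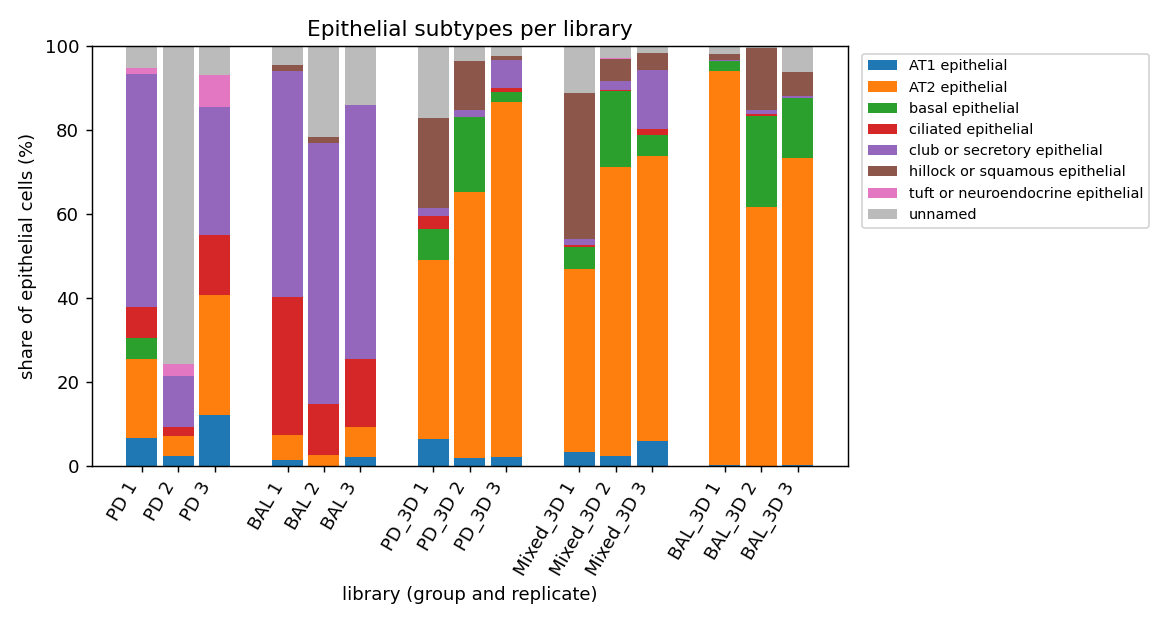
Share of epithelial cells (%) of each subtype in each of the 15 libraries, stacked to 100%. AT2-like cells average 5.22% in BAL and 76.1% in BAL_3D, and AT1-like cells average 0.236% in BAL_3D against 3.62% in PD_3D.

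Epithelial cells of PD_3D organoids were compared with those of fresh PD lung. Genes of glycolysis and hypoxia were among those that rose. Ndrg1, a hypoxia-induced gene, rose from 8.91 ± 4.19 to 338 ± 80.9 CPM (SD, n = 3 each; log2 fold change 5.26 ± 0.458 SE, adjusted p = 6.95e-06). Bnip3, a mitochondrial stress gene of the same response, rose by 3.59 ± 0.267 and the glycolytic enzyme gene Pgam1 by 2.73 ± 0.240. Scgb1a1, the main club cell secretory gene, went from 405000 ± 55700 to 7438 ± 6267 CPM (-5.77 ± 0.840, adjusted p = 0.0002). In all, 3003 genes rose and 3224 fell of 16373 tested (6227 together; 5247 within 8.0.1; 5976 with the replicates as paired blocks). In AT2-like cells alone, 1885 rose and 1696 fell.

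Of 23 tested glycolysis and hypoxia genes, 21 rose and none fell, and the same counts passed when adjusted over the list alone. The median log2 fold change was 2.51 (camera adjusted p = 3.48e-17, adjusted p = 0.0540 with an estimated correlation); Pfkl (0.60) and Hk1 (0.15) did not pass. Of 21 cholesterol synthesis genes 19 rose and none fell (20 and none adjusted over the list alone; median 1.58, camera adjusted p = 7.33e-09, adjusted p = 0.308 with an estimated correlation). They included Dhcr7 (2.25 ± 0.263), Cyp51 (2.19 ± 0.271) and Nsdhl (1.51 ± 0.222), while Srebf2 (-0.02) and Mvk (0.83) did not pass. Of 19 proliferation genes 16 rose and 1 fell (17 and 1 adjusted over the list alone; median 2.23, camera adjusted p = 3.95e-06, adjusted p = 0.333 with an estimated correlation), with Mki67 at 2.53 ± 0.406, Mcm3 at 1.57 ± 0.217 and Mcm2 at 1.81 ± 0.291. Cenpf (-0.56) and Tyms (0.98) did not pass. In AT2-like cells alone 5 of 19 proliferation genes rose and none fell (median 1.13, camera adjusted p = 0.000884, adjusted p = 0.532 with an estimated correlation), and Mki67 did not pass (1.13, adjusted p = 0.139). Of the glycolysis and cholesterol genes, 20 of 23 and 12 of 21 rose there (medians 2.56 and 1.18).

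Airway genes parted. Of 13 club and secretory genes 12 fell and none rose (13 and none adjusted over the list alone; median -4.27, camera adjusted p = 1.12e-05, adjusted p = 0.326 with an estimated correlation), among them Cldn10 (-6.84 ± 0.893) and Cyp2f4 (-7.57 ± 1.03); Spdef (-0.87) did not pass. In AT2-like cells 3 of the 13 fell (median -1.03, camera adjusted p = 0.0515, adjusted p = 0.667 with an estimated correlation), and named club cells were 32.8% of PD and 3.42% of PD_3D. Of 10 ciliated genes 9 fell and none rose (10 and none adjusted over the list alone; median -4.05, camera adjusted p = 0.000147, adjusted p = 0.451 with an estimated correlation), among them Tekt1 (-3.65 ± 0.490), Rsph1 (-3.51 ± 0.521) and Dnah5 (-5.32 ± 1.02). Dynlrb2 (-4.00, adjusted p = 0.0502) did not pass. In AT2-like cells alone Tekt1 (adjusted p = 0.940) and Rsph1 (adjusted p = 0.986) did not pass, and 2 of 9 tested ciliated genes fell (median -2.30, camera adjusted p = 0.0278, adjusted p = 0.532 with an estimated correlation). Of 12 hillock and squamous genes 8 rose and none fell (10 and none adjusted over the list alone). Their median was 7.38, or 5.42 with genes absent from PD at their bound (camera adjusted p = 0.000147, adjusted p = 0.448 with an estimated correlation). Lypd3 rose by 3.10 ± 0.558 and the desmosome gene Dsg3 by 5.67 ± 1.11, and Anxa1 (0.77) and Ecm1 (1.89) did not pass. In AT2-like cells Dsg3 was at 0.82 (adjusted p = 0.687), and 1 of 9 tested hillock and squamous genes rose (median 7.79, camera adjusted p = 0.0477, adjusted p = 0.532 with an estimated correlation). That median equals the fold of Krt16, which had no count in PD, so neither a kept nor a lost rise is shown.

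Surfactant genes depended on which cells were summed. Over all epithelial cells 10 of 16 AT2 and surfactant genes rose and none fell (10 and none adjusted over the list alone; median 1.23, camera adjusted p = 0.000840, adjusted p = 0.326 with an estimated correlation). They included the lipid synthesis genes Fasn (1.86 ± 0.302) and Scd (3.63 ± 0.640) and the lamellar body gene Lamp3 (1.64 ± 0.345). Sftpc (1.25 ± 1.16, adjusted p = 0.418) and Sftpa1 (0.99 ± 0.570, adjusted p = 0.189) did not pass. In AT2-like cells alone the list turned: 9 of 16 fell, none rose, and the median was -1.07 (camera adjusted p = 4.52e-05, adjusted p = 0.328 with an estimated correlation). There Lamp3 was at -1.23 (adjusted p = 0.00805), Fasn at -0.12 (adjusted p = 0.808), and Scd at 0.62 did not pass (adjusted p = 0.360). AT2-like cells of PD and PD_3D lay in separate subclusters, 490 and 375 PD cells in 2 without a PD_3D cell and 2485 and 1818 PD_3D cells in 2 without a PD cell. The turn is therefore not shown to be a change within 1 kind of AT2-like cell.

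Sprr1a was at least 2220-fold, Krt16 at least 784-fold and the glutamate transporter gene Slc1a6 at least 1290-fold higher in PD_3D, against a floor of 3 counts over the PD group, where each had no count. These were among the largest rises. Cnfn was 3030-fold higher (95% counting interval 840 to 25000) and Krtdap 1200-fold higher (332 to 9920), and Krt13 rose by 9.09 ± 1.71. None of these except Slc1a6 passed in AT2-like cells alone (adjusted p from 0.113 for Krt16 to 0.228 for Krt13). The fold of Krt13 there was 8.49. Free RNA was not removed from these sums, so for the lost calls neither a kept nor a lost rise is shown. The largest falls were Cyp2a3 (-11.78 ± 0.646), Clca1 (-10.52 ± 1.17), T2 (-9.32 ± 0.827) and Lrmp (-8.85 ± 0.865), and Tbxt was 1720-fold lower (475 to 14200). Immunoglobulin Ighm also fell (-9.51 ± 1.30), beside markers of other cell types: 9 of 12 lymphocyte and 7 of 10 endothelial markers fell, and of 13 macrophage markers 8 fell and 2 rose.

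Epithelial cells of BAL_3D organoids were compared with the few epithelial cells of the lavage. The subtypes differed, with club or secretory cells the most frequent in BAL and AT2-like cells in BAL_3D. The 12 AT2-like cells of BAL were too few for a fit of their own, so changes within a cell type and a change of cell types are not separated here. The phosphate transporter gene Slc34a2 of AT2 cells rose from 23.8 ± 25.1 to 1223 ± 187 CPM (SD, n = 3 each; log2 fold change 5.68 ± 0.584 SE, adjusted p = 2.19e-05), and Lamp3 from 50.3 ± 22.0 to 581 ± 152 CPM. The dividing-cell gene Mki67 rose from 3.06 ± 2.61 to 131 ± 32.3 CPM (5.72 ± 0.652). Scgb1a1 went from 181000 to 2152 CPM (-6.39 ± 0.865, adjusted p = 0.000147). In all 2158 genes rose and 2167 fell of 16373 tested (4325 together; 4284 when the fit used only 8.0.1 libraries; 4088 with the replicates as a block, although the numbers did not pair these libraries). With DESeq2 size factors 1610 rose and 2393 fell, and by DESeq2 1539 and 2946. The BAL sums rest on 227 cells and 1532040 UMIs, against 276694385 UMIs in BAL_3D.

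Of 16 AT2 and surfactant genes 14 rose and none fell (15 and none adjusted over the list alone; median 2.91, camera adjusted p = 1.03e-14, adjusted p = 0.0857 with an estimated correlation), Acsl4 (2.94 ± 0.337) among them; Lyz2 (1.26) and Sftpd (-0.42) did not pass. All 10 ciliated genes fell, also when adjusted over the list alone (median -7.39, camera adjusted p = 1.55e-12, adjusted p = 0.154 with an estimated correlation), with Rsph1 at -6.00 ± 0.594, Tekt1 at -4.94 ± 0.545 and Ccdc153 at -8.38 ± 1.18. Of 13 club and secretory genes 10 fell and none rose (12 and none adjusted over the list alone; median -4.86, camera adjusted p = 3.58e-10, adjusted p = 0.0892 with an estimated correlation), with Cldn10 at -6.96 ± 0.934 and Cyp2f4 at -6.13 ± 0.967. Scgb3a1 (-1.87) and Hp (-1.56) did not pass. Of 19 proliferation genes 13 rose and none fell (18 and none adjusted over the list alone; median 2.62, camera adjusted p = 1.96e-09, adjusted p = 0.242 with an estimated correlation). Mcm6 rose by 2.34 ± 0.340, Mcm2 was 12.7-fold higher (95% counting interval 4.33 to 61.4), and Cenpf (1.24) and Pcna (1.19) did not pass.

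Metabolic genes moved as well. Of 23 glycolysis and hypoxia genes 14 rose and none fell (17 and none adjusted over the list alone; median 1.57, camera adjusted p = 4.36e-09, adjusted p = 0.112 with an estimated correlation): P4ha1 by 3.48 ± 0.439, Bnip3 by 2.19 ± 0.280 and Pgam1 by 1.86 ± 0.242. Hk2 (0.93) and Ankrd37 (1.15) did not pass. Of 21 cholesterol synthesis genes 11 rose and none fell (15 and none adjusted over the list alone; median 1.24, camera adjusted p = 4.65e-05, adjusted p = 0.421 with an estimated correlation), among them Dhcr7 (1.92 ± 0.362), Cyp51 (1.5 ± 0.286) and the regulator Srebf2 (from 56.3 ± 14.1 to 114 ± 12.5 CPM, adjusted p = 0.00223); Fdps (1.34) and Idi1 (1.00) did not pass. Of 13 genes of FGF and ERK feedback 7 rose and none fell (8 and none adjusted over the list alone; median 1.79, camera adjusted p = 0.000315, adjusted p = 0.169 with an estimated correlation), with Etv5 at 3.14 ± 0.583, Spred1 at 1.79 ± 0.321 and Dusp6 at 1.78 ± 0.336. Egr1 (2.27) and Phlda1 (0.79) did not pass.

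Krt5, the basal keratin gene, was at least 127-fold higher in BAL_3D and Krt13 at least 67.8-fold, against a floor of 3 counts over the BAL group. The same bound was 35.3-fold for Atp6v0a4, 40.4-fold for the cystine transporter gene Slc7a11, 28.3-fold for Tmem213 and 32.1-fold for Fam25a. Krt5 did not pass without BAL 1, BAL 2, BAL 3 or BAL_3D 3 (adjusted p = 0.0566, 0.0772, 0.0798 and 0.0506), nor Krt13 without BAL 2 or BAL 3 (adjusted p = 0.0636 and 0.0645). The largest falls were Itln1, 578000-fold lower (198000 to 2800000), Rgs13, 19500-fold lower (6620 to 95100), Rgs5, at least 4390-fold lower, Pla2g4c (-17.01 ± 1.56), Clca1 (-14.02 ± 1.30) and Cyp2a3 (-13.39 ± 0.690). Genes of alveolar macrophages moved beside them: 14 of 18 fell (median -4.86, camera adjusted p = 1.96e-09, adjusted p = 0.112 with an estimated correlation). The complement and scavenger list had a median of 2.11 and a mean of 1.06, but camera placed it lower (adjusted p = 0.0181, adjusted p = 0.422 with an estimated correlation) and 4 of its 10 genes fell.

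The change from fresh cells to organoid differed between the lavage and the dissociated lung for 385 genes, 245 with a higher and 140 with a lower change in lavage cells (interaction test in edgeR). It was 149 genes within 8.0.1 and 185 with replicates as a block. The excess of higher changes rests on the scaling and the filter, with 152 higher and 142 lower with DESeq2 size factors and 126 of each with no gene filter. The fresh epithelial sums also differ in subtypes (AT2-like cells 5.22% in BAL and 17.3% in PD), so a different starting mix is not separated from a different response. The count was 47 without PD_3D 3, 70 without PD 3, 96 without BAL_3D 3, 97 without BAL 2, 106 without PD 1 and 135 without PD_3D 2. It was 169 without BAL 3, 201 without BAL_3D 1, 224 without BAL 1, 239 without PD 2 and 1148 without PD_3D 1. Slc34a2 gained 3.84 ± 0.704 more in lavage cells (adjusted p = 0.0191), while Ndrg1 gained less by -2.77 ± 0.618 (adjusted p = 0.0390).

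**Figure D3:**
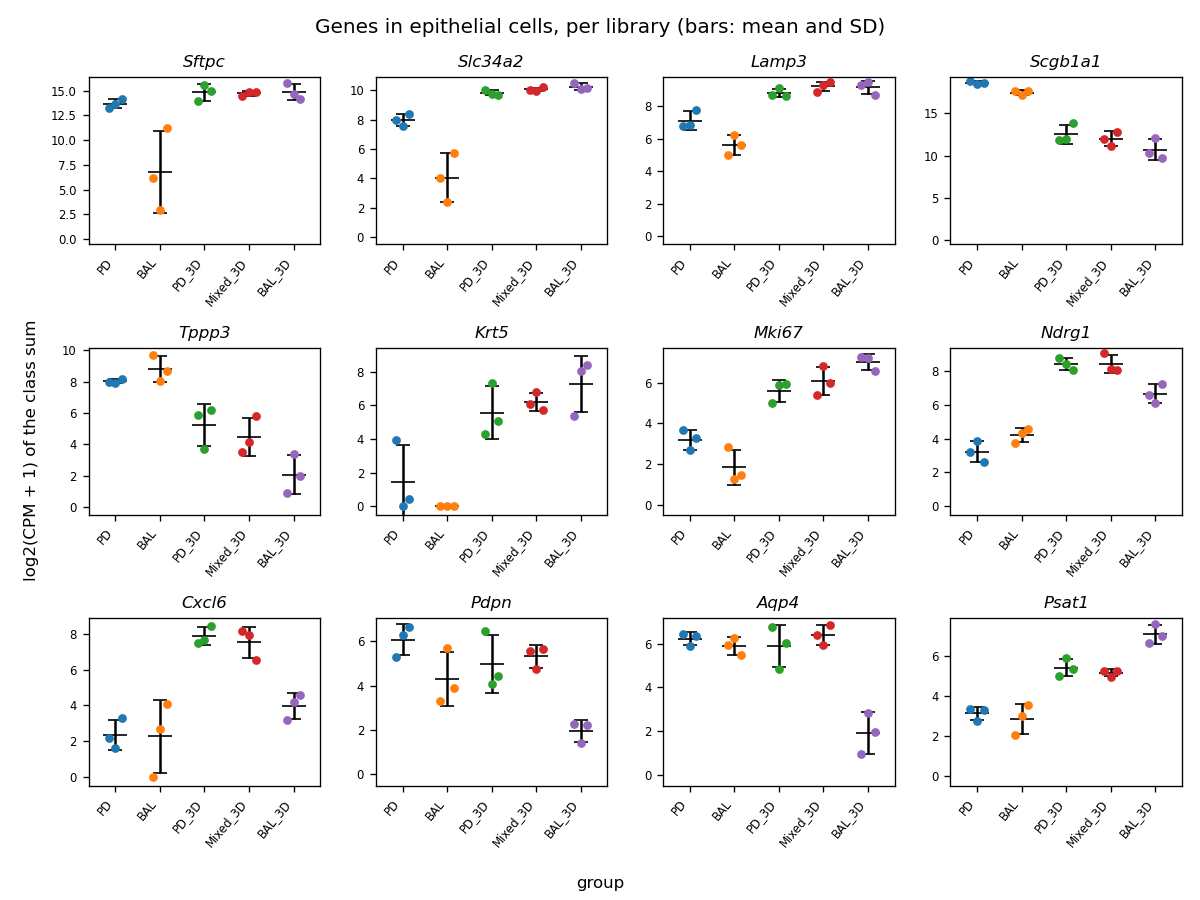
log2(CPM + 1) of 12 genes in the epithelial sum of each library; points are libraries and bars the mean and SD of 3. Slc34a2 averages 23.8 CPM in BAL and 1223 in BAL_3D, and Aqp4 averages 3.28 CPM in BAL_3D against 67.5 in PD_3D and 86.5 in Mixed_3D.

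Epithelial cells of BAL_3D and PD_3D organoids came from different seeded cells and the same medium. Aqp4, a water channel gene, was lower in BAL_3D, at 3.28 ± 2.64 against 67.5 ± 40.6 CPM (SD, n = 3 each; log2 fold change -4.35 ± 0.621 SE, adjusted p = 0.0164). The neutrophil chemokine gene Cxcl6 was at 16 ± 7.72 against 242 ± 92.5 CPM (-3.92 ± 0.636, adjusted p = 0.0186), and the AT1 gene Pdpn at 3.06 ± 1.23 against 41.7 ± 40.8 CPM (-3.77 ± 0.696, adjusted p = 0.0272). The serine synthesis gene Psat1 was higher at 138 ± 48.3 against 42.7 ± 13.4 CPM (1.69 ± 0.300, adjusted p = 0.0235), and the folate gene Mthfd2 at 87.6 ± 33.3 against 18.7 ± 4.06 CPM (2.23 ± 0.390, adjusted p = 0.0235). In all 32 genes were higher and 103 lower of 16373 tested (135 together), and 45 passed within 8.0.1.

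The remaining largest differences were Rapgef5 (1.96 ± 0.396), Knl1 (1.81 ± 0.330), Acot2 (1.75 ± 0.327) and Ddah1 (1.58 ± 0.315) upward, and Tf (-3.15 ± 0.405), Glis3 (-3.15 ± 0.366) and Cox4i2 (-2.72 ± 0.483) downward. The count was 0 without BAL_3D 3, 29 without PD_3D 3, 77 without BAL_3D 1, 80 without PD_3D 1, 243 without BAL_3D 2 and 276 without PD_3D 2. At an unadjusted p under 0.05 there were 2726 genes, DESeq2 called 1060, and an edgeR fit of these groups alone called 0. Without BAL_3D 3 no gene named for this comparison passed (adjusted p from 0.0683 for Tf to 0.132 for Col5a2). Aqp4, Cxcl6, Tf, Glis3 and Cx3cl1 passed without each other library. The rest missed the threshold without at least 1 of PD_3D 3 (adjusted p from 0.0566 for Col5a2 to 0.151 for Ddah1), PD_3D 1 (0.0545 for Pdpn to 0.0945 for Rapgef5), BAL_3D 1 (0.0625 for Loxl2 to 0.0944 for Col5a2) or BAL_3D 2 (0.0539 for Cox4i2 and 0.0722 for Col5a2). Within 8.0.1 the same 5 genes, Cox4i2 and Mthfd2 passed and the rest did not (0.0716 for Loxl2 to 0.125 for Rapgef5). After subtraction of the empty-barcode profile 47 genes passed, and Mthfd2, Rapgef5, Knl1, Acot2, Psat1, Ddah1, Pdpn, Cox4i2, Col5a2 and Ccl28 did not (0.0546 for Acot2 to 0.0987 for Knl1). Their folds did not shrink by much: Mthfd2 was then at 2.22, Psat1 at 1.71, Rapgef5 at 1.93, Knl1 at 1.76 and Pdpn at -3.86, and Col5a2 was at -6.74.

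Several lists stood apart as groups. Of 28 extracellular matrix genes 2 were lower and none higher (9 and none adjusted over the list alone; median -1.38, camera adjusted p = 9.42e-07, adjusted p = 0.185 with an estimated correlation; median -1.07 within 8.0.1). These were Loxl2 (-3.00 ± 0.517, adjusted p = 0.0227) and the collagen gene Col5a2 (-4.99 ± 1.02, adjusted p = 0.0387); Col4a1 (0.35) and Timp3 (-1.10) did not pass. Of 32 chemokine and cytokine genes 3 were lower and none higher (14 lower and 1 higher adjusted over the list alone; median -1.54, camera adjusted p = 1.87e-06, adjusted p = 0.155 with an estimated correlation; median -1.25 within 8.0.1). Beside Cxcl6 these were Cx3cl1 (-1.88 ± 0.301, adjusted p = 0.0186) and Ccl28 (-3.06 ± 0.593, adjusted p = 0.0330), while Cxcl3 (-1.69) and Cxcl1 (-1.89) did not pass. Of 11 AT1 genes only Pdpn was lower (3 adjusted over the list alone; median -1.07, camera adjusted p = 0.000146, adjusted p = 0.204 with an estimated correlation; median -0.81 within 8.0.1), and Hopx (-0.89) and Vegfa (-0.90) did not pass. No single gene passed among 19 transitional epithelial genes (7 lower adjusted over the list alone; median -1.02, camera adjusted p = 7.84e-06, adjusted p = 0.155 with an estimated correlation; median -0.99 within 8.0.1), with S100a6 at -0.55 and Krt8 at -0.78. None passed among 10 ciliated genes (9 lower adjusted over the list alone; median -2.98, camera adjusted p = 1.62e-07, adjusted p = 0.211 with an estimated correlation; median -2.67 within 8.0.1), with Tppp3 at -3.41 and Dynlrb2 at -3.00. Nor did any of 19 proliferation genes pass (2 higher adjusted over the list alone; median 0.82, camera adjusted p = 5.62e-06, adjusted p = 0.316 with an estimated correlation), with Mki67 at 1.41 (adjusted p = 0.0899), Ube2c at 1.11 and Top2a at 1.26. Among AT2-like cells 6 of 32 chemokine, 3 of 25 matrix, 2 of 11 AT1 and 1 of 19 transitional genes were lower and none higher (camera adjusted p = 1.09e-08, 1.70e-07, 4.35e-07 and 2.33e-07, adjusted p = 0.102, 0.204, 0.102 and 0.102 with an estimated correlation). Markers of other cell types were lower beside these: 3 mesothelial markers (median -2.89) and 7 neutrophil markers (median -2.82), none passing, each with a camera adjusted p of 0.0180 (0.211 with an estimated correlation). In AT2-like cells their medians were -4.84 and -2.41 (camera adjusted p = 0.00340 and 0.00934, adjusted p = 0.102 and 0.117 with an estimated correlation). PD_3D held 73 mesenchymal cells and BAL_3D 1. After subtraction of the empty-barcode profile the extracellular matrix list had a median of -1.29 (camera adjusted p = 0.000460, adjusted p = 0.164 with an estimated correlation).

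Epithelial cells of Mixed_3D and PD_3D organoids differed in the lavage cells added to the seeded lung suspension. No gene passed in edgeR, with 196 genes at an unadjusted p under 0.05, 2 genes in DESeq2, 0 with replicates as a paired block, 0 within 8.0.1 and 2 in a paired fit of these groups alone. In the simulation of this comparison 18% of 2-fold and 93% of 4-fold changes were called. The simulation gave genes of 1 level a common spread and had no structure by replicate number. It therefore does not limit the changes in the real libraries. The lysozyme gene Lyz2 was at 12720 ± 1218 against 15170 ± 5589 CPM (SD, n = 3 each; log2 fold change -0.25 ± 0.473 SE, adjusted p = 1). Macrophage markers stood higher as a group, with none of 13 passing and 7 higher when adjusted over the list alone (median 2.22, camera adjusted p = 1.93e-17, adjusted p = 0.0858 with an estimated correlation). Their members were scarce, with Mrc1 at 2.13 ± 1.11 against 0.0773 ± 0.0571 CPM, C1qb at 1.30 ± 1.08 against 0.0448 ± 0.0492, and Cd68 at 25.6 ± 33.7 against 6.61 ± 5.93. Mrc1 stood at 0.0152 and C1qb and C1qc at 0.00987 and 0.00970 of their level in empty barcodes, and after subtraction of the empty-barcode profile the group turned lower (camera adjusted p = 0.0132).

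Epithelial cells of Mixed_3D and BAL_3D organoids differed in the lung cells seeded beside the lavage. Aqp4 was higher in Mixed_3D, at 86.5 ± 26.7 against 3.28 ± 2.64 CPM (SD, n = 3 each; log2 fold change 4.71 ± 0.631 SE, adjusted p = 0.00950). Pdpn was at 40.8 ± 13.2 against 3.06 ± 1.23 CPM (3.74 ± 0.695, adjusted p = 0.0276) and Cxcl6 at 205 ± 101 against 16 ± 7.72 CPM (3.68 ± 0.629, adjusted p = 0.0207). The serine synthesis genes Psat1 (-1.99 ± 0.303, adjusted p = 0.0156) and Psph (-1.77 ± 0.315, adjusted p = 0.0246), the folate gene Mthfd2 (-2.34 ± 0.392, adjusted p = 0.0199) and the cysteine synthesis gene Cth (-2.67 ± 0.522, adjusted p = 0.0326) were lower. In all 103 genes were higher and 22 lower (125 together; 39 within 8.0.1; 117 with the replicates as a block, although the numbers did not pair these libraries).

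The cytokine gene Il24 (3.62 ± 0.656) was among the largest rises, and Itln1 was 1810-fold higher (95% counting interval 620 to 8800). Rapgef5 (-1.84 ± 0.395) and Ddah1 (-1.46 ± 0.314) were among the largest falls. The count was 0 without BAL_3D 3, 41 without Mixed_3D 1, 67 without BAL_3D 1, 74 without Mixed_3D 3 and 78 without Mixed_3D 2. At an unadjusted p under 0.05 there were 2353 genes, DESeq2 called 821, and edgeR on these groups alone called 0. Without BAL_3D 3 no gene named for this comparison passed (adjusted p from 0.0643 for Psat1 to 0.225 for Itln1). Aqp4, Psat1 and Ltbp2 passed without each other library. The rest missed the threshold without at least 1 of BAL_3D 1 (adjusted p from 0.0581 for Cxcl6 to 0.124 for Itln1), BAL_3D 2 (0.0502 for Il24 to 0.0976 for Itln1), Mixed_3D 1 (0.0504 for Cxcl6 to 0.118 for Ddah1), Mixed_3D 2 (0.0630 for Mthfd2 to 0.120 for Ddah1) or Mixed_3D 3 (0.0504 for Il24 to 0.148 for Ddah1). Within 8.0.1 Aqp4, Pdpn, Mthfd2, Psat1, Psph, Cx3cl1 and Ltbp2 passed and the rest did not (0.0529 for Ccl2 to 0.164 for Ddah1). After subtraction of the empty-barcode profile 55 genes passed, and Il24, Pdpn, Mthfd2, Cth, Ddah1, Itln1, Rapgef5 and Ccl2 did not (0.0568 for Il24 to 1 for Ccl2). Ccl2 was then at 0, while Il24 was at 3.71, Pdpn at 3.87, Mthfd2 at -2.33 and Cth at -2.54. With the replicates as a block Itln1 (0.0855), Cth (0.0517) and Rapgef5 (0.0503) did not pass.

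Of 32 chemokine and cytokine genes 4 were higher and none lower (15 and none adjusted over the list alone; median 1.95, camera adjusted p = 1.88e-10, adjusted p = 0.0644 with an estimated correlation). Cx3cl1 was higher by 1.86 ± 0.301 and Ccl2 by 4.32 ± 0.724, Ccl2 at 0.0338 of its level in empty barcodes; Cxcl3 (1.38) and Cxcl1 (1.62) did not pass. Of 15 TGF-beta target genes 1, the matrix gene Ltbp2 (6.22 ± 0.747, adjusted p = 0.00950), was higher and none lower (8 and none adjusted over the list alone; median 1.27, camera adjusted p = 5.52e-07, adjusted p = 0.0740 with an estimated correlation). Itgb6 (1.35) and Col4a1 (-0.21) did not pass. Of 11 AT1 genes only Pdpn was higher (5 adjusted over the list alone; median 1.44, camera adjusted p = 5.34e-06, adjusted p = 0.110 with an estimated correlation), while Hopx (1.44) and Vegfa (0.84) did not pass. None of 28 extracellular matrix genes passed (11 higher adjusted over the list alone; median 1.70, camera adjusted p = 3.20e-08, adjusted p = 0.0846 with an estimated correlation). None of 19 transitional epithelial genes passed (8 higher adjusted over the list alone; median 1.16, camera adjusted p = 4.49e-07, adjusted p = 0.0740 with an estimated correlation). Loxl2 (2.23), Timp3 (1.54), S100a6 (0.59) and Krt8 (0.33) were among those that did not pass. Among AT2-like cells 7 of 32 chemokine, 3 of 11 AT1, 5 of 25 matrix and 3 of 19 transitional genes were higher and none lower (medians 2.09, 2.23, 2.09 and 1.24, camera adjusted p = 9.61e-16, 2.21e-11, 2.21e-11 and 1.31e-08). With an estimated correlation the adjusted p was 0.0499 for the chemokine and AT1 lists, 0.0861 for the matrix and 0.0625 for the transitional list. Markers of other cell types were higher beside these lists. In the same cells the medians were 1.26 for macrophage, 2.08 for mesenchymal, 2.33 for neutrophil and 3.41 for mesothelial markers (camera adjusted p = 0.00145, 0.0265, 0.00153 and 0.00292, adjusted p = 0.256, 0.256, 0.0625 and 0.0625 with an estimated correlation). After subtraction of the empty-barcode profile the chemokine and extracellular matrix lists had medians of 1.10 and 1.40 (camera adjusted p = 0.000183 and 0.000439, adjusted p = 0.129 for each with an estimated correlation), and macrophage markers one of 0.38 (camera adjusted p = 0.777).

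Macrophages of BAL were washed from the airspace and those of PD came from the whole dissociated lung, and they lay in largely separate clusters. The largest cluster held 5565 BAL and 35 PD cells. PD cells led in 5 others, the 3 largest with 1235 against 133, 638 against 40, and 412 against 53 in a cluster led by C1qa, C1qb and RT1-Da. A change within 1 kind of macrophage and a different mix of macrophages and monocytes are therefore not separated below. The complement genes C1qa, C1qb and C1qc were lower in BAL: C1qa at 2.44 ± 0.797 against 271 ± 90.8 CPM (SD, n = 3 each; log2 fold change -6.80 ± 0.888 SE, adjusted p = 0.0002), C1qb by -7.32 ± 1.06 and C1qc by -7.36 ± 1.03. Antigen presentation gene RT1-Ba was at 13.4 ± 5.60 against 717 ± 410 CPM (-5.75 ± 1.05, adjusted p = 0.00173) and the cytokine gene Il1b at 24.3 ± 14.3 against 371 ± 186 CPM (-3.94 ± 0.578, adjusted p = 0.000403). In all 379 genes were higher and 2370 lower in BAL of 14712 tested (2749 together; 1643 within 8.0.1; 2592 with the replicates as a block, although the numbers did not pair these libraries). After subtraction of the empty-barcode profile 45 were higher and 720 lower. The balance moved with the scaling and the groups fitted: 146 were higher and 2618 lower with DESeq2 size factors, 197 and 2589 by DESeq2, and 982 and 2422 in a fit of these groups alone. The count was 1828 without BAL 3.

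Of 11 complement and scavenger genes 7 were lower and none higher (7 and none adjusted over the list alone; median -6.70, camera adjusted p = 7.61e-07, adjusted p = 0.0408 with an estimated correlation), Stab1 (-7.14 ± 0.670) and Colec12 (-5.79 ± 0.539) among them, Colec12 at 0.282 of its level in empty barcodes; Msr1 (0.32) did not pass. Of 9 MHC class II genes 8 were lower and none higher (8 and none adjusted over the list alone; median -5.75, camera adjusted p = 5.36e-05, adjusted p = 0.149 with an estimated correlation), with RT1-DOa at -6.65 ± 0.830 and the regulator Ciita at -5.08 ± 0.727, and RT1-Db2 (0.42) did not pass. Of 23 inflammatory macrophage genes 16 were lower and none higher (20 and none adjusted over the list alone; median -2.74, camera adjusted p = 1.96e-09, adjusted p = 0.0707 with an estimated correlation), with Tlr2 at -1.96 ± 0.276 and Cd86 at -4.07 ± 0.588; Irf5 (-0.56) and Cxcl3 (-0.99) did not pass. Of 30 chemokine and cytokine genes 16 were lower and none higher (19 and none adjusted over the list alone). Their median was -2.64, or -2.68 with scarce genes at their bound (camera adjusted p = 2.32e-06, adjusted p = 0.0823 with an estimated correlation). Cxcl1 was lower by -7.88 ± 1.22, and Ccl20 was 882-fold lower (153 to 35300), at 0.0381 of its level in empty barcodes; Ccl6 (0.56) and Il18 (0.61) did not pass. Of 20 dissociation and immediate early genes 13 were lower and none higher (15 and none adjusted over the list alone; median -2.08, camera adjusted p = 7.24e-06, adjusted p = 0.158 with an estimated correlation), with Egr1 at -4.41 ± 0.656, Atf3 at -2.55 ± 0.376 and Jun at -2.41 ± 0.374; Btg2 (-1.35) and Jund (-0.73) did not pass.

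Genes of other cell types moved with these. All 13 club and secretory genes were lower in BAL macrophages (camera adjusted p = 1.74e-14, adjusted p = 0.0707 with an estimated correlation), as were 9 of 11 AT1 genes (camera adjusted p = 9.02e-13, adjusted p = 0.0408 with an estimated correlation), 7 of 10 endothelial and 10 of 16 lymphocyte markers. All 4 red blood cell markers were higher (median 6.88). Among lower-called members of lists of other cell types, 65 of 72 stood in PD macrophages under 50% of their level in empty barcodes of the same libraries, against 2 of 16 inflammatory genes. The largest falls were Cd226 (log2 fold change -10.33, adjusted p = 6.60e-05), Cxcl1, C1qc, C1qb, Cxcl2 (-7.10 ± 1.26) and Dgkg (-6.88 ± 0.532), and the largest rises Ctsk (2.00 ± 0.507), Wfdc21 (1.77 ± 0.386), C5ar2 (1.72 ± 0.384), Cdkn3 (1.44 ± 0.450), Ska2 (1.39 ± 0.424) and Gdpd1 (1.32 ± 0.279). Of the rises only Wfdc21 passed after subtraction of the empty-barcode profile; Ctsk (adjusted p = 0.0707), C5ar2 (0.0560), Gdpd1 (0.110), Cdkn3 (0.523) and Ska2 (0.158) did not, at folds of 1.88, 1.54, 1.13, 1.26 and 1.27. Within 8.0.1 Ctsk (0.0594), Ska2 (0.0704) and Cdkn3 (0.122) did not pass. Ctsk did not pass without PD 2 (0.0554) or BAL 2 (0.0592). Cdkn3 did not pass without any 1 of the PD or BAL libraries (0.0786 without BAL 3 to 0.175 without PD 1), nor Ska2 without any of them but PD 3 (0.0637 without BAL 1 to 0.132 without PD 1).

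**Figure D4:**
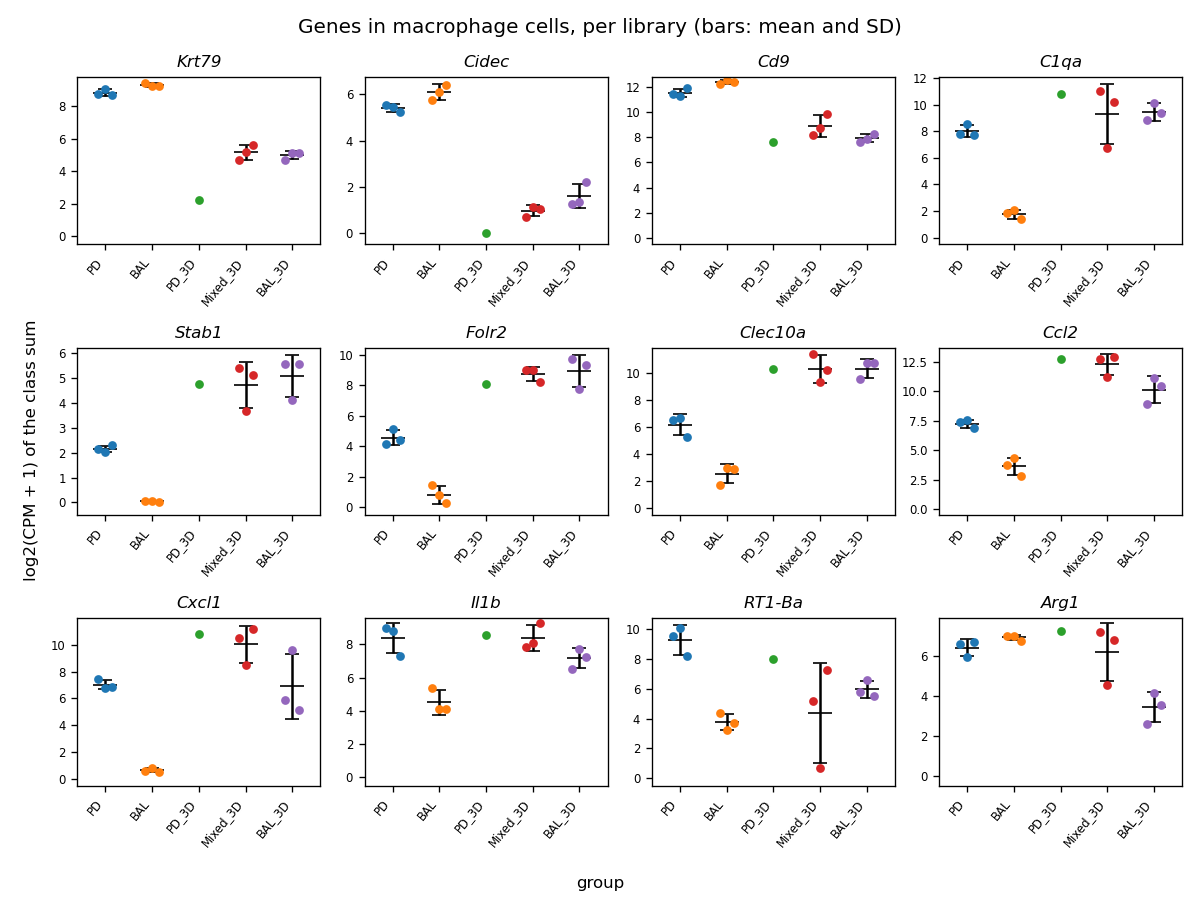
log2(CPM + 1) of 12 genes in the macrophage sum of each library with at least 20 macrophages; points are libraries and bars the mean and SD, with 1 library in PD_3D. C1qa averages 2.44 CPM in BAL, 271 in PD and 746 in BAL_3D, and Cd9 falls from 5351 CPM in BAL to 244 in BAL_3D.

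Macrophages of BAL_3D were compared with those of BAL. They shared almost no cluster: 937 BAL_3D cells lay in one with 4 BAL cells, and the largest BAL cluster held no BAL_3D cell. A change of airspace macrophages and the outgrowth of a minor kind are not separated here. Genes of alveolar macrophage identity fell: Cd9 from 5351 ± 574 to 244 ± 56.8 CPM (SD, n = 3 each; log2 fold change -4.46 ± 0.436 SE, adjusted p = 2.05e-05), Krt79 from 640 ± 49.5 to 31.2 ± 5.20 CPM (-4.38 ± 0.283) and the lipid droplet gene Cidec by -5.08 ± 0.368. The complement gene C1qa rose from 2.44 ± 0.797 to 746 ± 344 CPM (8.26 ± 0.946, adjusted p = 6.05e-05). The monocyte chemokine genes Ccl2 (6.79 ± 0.715) and Ccl7 (7.78 ± 0.780) rose as well. In all 1846 genes rose and 1528 fell of 14712 tested (3374 together; 3477 when the fit used only 8.0.1 libraries; 3016 with the replicates as a block, although the numbers did not pair these libraries).

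Of 20 alveolar macrophage identity genes 14 fell and 1 rose (14 and 1 adjusted over the list alone; median -2.03, camera adjusted p = 3.07e-11, adjusted p = 0.0493 with an estimated correlation); Mrc1 (0.28) and Serpinb1a (-0.44) did not pass. Of 11 complement and scavenger genes 7 rose and 2 fell (7 and 2 adjusted over the list alone; median 6.09, camera adjusted p = 1.75e-05, adjusted p = 0.0537 with an estimated correlation), Colec12 (6.09 ± 0.546) among them, and Msr1 (0.74) and Cd5l (3.94) did not pass. Of 25 alternative macrophage genes 12 rose and 3 fell (12 and 3 adjusted over the list alone). Their median was 0.74, or 0.86 with scarce genes at their bound (camera adjusted p = 6.25e-05, adjusted p = 0.189 with an estimated correlation), and the lectin gene Clec10a rose by 8.01 ± 0.747. Of 15 p53 and senescence genes 8 rose and 1 fell (9 and 1 adjusted over the list alone; median 0.88, camera adjusted p = 7.52e-05, adjusted p = 0.0598 with an estimated correlation), with Gdf15 at 4.89 ± 0.467 and Cdkn1a at 3.23 ± 0.431. Igfbp3 rose by 6.96 ± 0.844 and stood at 0.217 of its level in empty barcodes; Bax (-0.31) and Ccng1 (0.92) did not pass. Of 23 inflammatory macrophage genes 9 rose and 1 fell (11 and 1 adjusted over the list alone; median 1.35, or 1.72 with scarce genes at their bound, camera adjusted p = 0.00276, adjusted p = 0.337 with an estimated correlation), with Tlr2 at 2.41 ± 0.284 and Irf5 at 1.35 ± 0.237; Ccl3 (0.84) and Nfkbia (1.09) did not pass. Of 30 chemokine and cytokine genes 13 rose and 2 fell (14 and 2 adjusted over the list alone; median 1.29, or 2.52 with scarce genes at their bound, camera adjusted p = 0.00946, adjusted p = 0.337 with an estimated correlation). The growth factor gene Csf1 rose by 4.26 ± 0.560, and Ccl9 (-0.50) did not pass.

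The largest rises were Ccl12 (12.19 ± 1.32), Stab1 (10.59 ± 0.669), Tmem37 (10.54 ± 0.757), the folate receptor gene Folr2 (9.55 ± 0.846), Pdgfc (9.03 ± 0.718) and Cxcl1 (8.99 ± 1.28). Against a floor of 3 counts over the BAL_3D group, Ltc4s, which makes leukotriene, was at least 598-fold lower, Tac1 at least 577-fold and Igfbp6 at least 150-fold. The scavenger receptor gene Olr1 fell by 9.97 on the log2 scale (± 0.666 SE), Htr2c was 1080-fold lower (95% counting interval 368 to 5220) and Fbp1 797-fold lower (143 to 31500). AT2 and surfactant genes rose in these macrophages as well, 11 of 16 with 2 lower (median 4.05, camera adjusted p = 3.46e-07, adjusted p = 0.133 with an estimated correlation). Sftpc stood at 255 CPM there, against 36300 in AT2-like cells of the same libraries. Free RNA of AT2-like cells is therefore not separated from a change of the macrophages.

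Macrophages of Mixed_3D were compared with those of BAL_3D. They too lay apart, with 1635 Mixed_3D and 94 BAL_3D cells in one cluster and 7 and 937 in another. Nothing traces Mixed_3D macrophages to the lavage or to the dissociated lung, so a different source is not separated from an effect of the other cells. Plxdc2 was lower in Mixed_3D, at 2.18 ± 0.477 against 26.3 ± 5.62 CPM (SD, n = 3 each; log2 fold change -3.58 ± 0.289 SE, adjusted p = 0.000188). Olr1 was higher at 26.9 ± 13.9 against 1.14 ± 1.59 CPM (5.78 ± 0.651, adjusted p = 0.00329), the arginase gene Arg1 at 92.6 ± 63.9 against 10.7 ± 5.61 CPM (3.43 ± 0.597, adjusted p = 0.0309) and the granule gene Srgn at 56.0 ± 20.8 against 7.81 ± 2.70 CPM (3.06 ± 0.338, adjusted p = 0.00329). Glycolysis gene Eno1 was at 619 ± 74.4 against 274 ± 40.0 CPM (1.18 ± 0.221, adjusted p = 0.0373). In all 44 genes were higher and 50 lower (94 together; 7 within 8.0.1; 30 with the replicates as a block, although the numbers did not pair these libraries).

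Trem3 (3.40 ± 0.564), Igfbp4 (3.17 ± 0.591) and Slc25a37 (2.27 ± 0.401) were also higher, and Slc10a6 (-2.35 ± 0.401), Pde7b (-2.00 ± 0.368), Fam198b (-1.97 ± 0.228), Apba1 (-1.83 ± 0.374) and Sntb2 (-1.62 ± 0.321) lower. The count was 3 without BAL_3D 1, 9 without Mixed_3D 1, 24 without BAL_3D 3, 217 without Mixed_3D 2 and 374 without BAL_3D 2. It was 576 with at least 50 cells per library, which leaves out Mixed_3D 2 and BAL_3D 2 (34 and 48 macrophages), 679 by DESeq2 and 2 in an edgeR fit of these groups alone. Plxdc2 and Fam198b passed without each library in turn. No other gene named for this comparison passed without BAL_3D 1 (adjusted p from 0.0501 for Srgn to 0.237 for Il23a). Srgn and Olr1 passed without each other library. The rest missed the threshold without at least 1 of Mixed_3D 1 (adjusted p from 0.0675 for Trem3 to 0.108 for Sntb2), BAL_3D 3 (0.0673 for Ifit3 to 0.0957 for Vegfa) or Mixed_3D 3 (0.0551 for Il23a to 0.0859 for Apba1). Within 8.0.1 Plxdc2, Fam198b, Srgn and Olr1 passed and the rest did not (0.0854 for Trem3 to 0.124 for Sntb2). These 4, Trem3, Slc25a37 and Slc10a6 passed with the replicates as a block and the rest did not (0.0557 for Arg1 to 0.0811 for Pgam1).

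Of 23 glycolysis and hypoxia genes 3 were higher and none lower (16 and none adjusted over the list alone; median 1.11, camera adjusted p = 4.22e-16, adjusted p = 0.0338 with an estimated correlation). Beside Eno1 these were Pgam1 (1.02 ± 0.204) and Vegfa (2.63 ± 0.532), Vegfa at 0.0538 of its level in empty barcodes, while Pgk1 (1.11) and Ldha (1.19) did not pass. Of 23 inflammatory macrophage genes 1, the cytokine gene Il23a (2.88 ± 0.544), was higher and none lower (14 higher and 1 lower adjusted over the list alone; median 1.77, camera adjusted p = 1.08e-08, adjusted p = 0.120 with an estimated correlation); Cxcl3 (3.69) and Ccl3 (1.96) did not pass. Of 30 chemokine and cytokine genes 1 was higher, Cxcl6, 58.2-fold (95% counting interval 19.8 to 283) and at 0.109 of its level in empty barcodes. Adjusted over the list alone 13 were higher and none lower (median 1.97, or 1.86 with scarce genes at their bound, camera adjusted p = 1.93e-08, adjusted p = 0.120 with an estimated correlation); Ccl2 (2.04) and Ccl6 (2.10) did not pass. Of 24 interferon response genes 1, Ifit3 (-1.97 ± 0.355), was lower and none higher (6 lower and 1 higher adjusted over the list alone; median -0.42, camera adjusted p = 0.000340, adjusted p = 0.120 with an estimated correlation), and Ifi27 (0.06) and Bst2 (-0.09) did not pass. After subtraction of the empty-barcode profile Vegfa (adjusted p = 0.457), Cxcl6 (0.308), Trem3 (0.107), Sntb2 (0.0835), Apba1 (0.0813), Igfbp4 (0.0688) and Il23a (0.0558) did not pass. Vegfa and Cxcl6 stood under or near 10% of their level in empty barcodes, the share subtracted, so little of their counts was left. The folds of the other 5 did not shrink by much: Trem3 was at 4.06, Sntb2 at -1.85, Apba1 at -1.85, Igfbp4 at 3.14 and Il23a at 4.18.

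Macrophages and mesenchymal cells of PD_3D were too few for a test, so 4 planned comparisons have none. PD_3D held 28, 0 and 7 macrophages in replicates 1, 2 and 3 and 54, 15 and 4 mesenchymal cells, and Mixed_3D held 257, 0 and 16 mesenchymal cells against 194, 506 and 198 in PD. Pooled over each group, Arg1 was at 171 CPM in the 35 PD_3D macrophages, 114 in Mixed_3D and 6.63 in BAL_3D, and C1qa at 2293, 1466 and 521 CPM. The mesenchymal class held different cells in each group. PD cells lay in 2 mesothelial clusters (619 and 139 cells) and a smooth muscle or pericyte cluster (139), and organoid cells in a cluster of 73 PD_3D, 272 Mixed_3D and 1 PD cell, so the levels that follow differ between cell types. In mesenchymal cells the pooled level of the collagen gene Col3a1 was 7930 CPM in PD, 317 in PD_3D and 207 in Mixed_3D, and that of Col1a1 2556, 857 and 1816 CPM. The smooth muscle gene Tagln was at 659, 2.36 and 9 CPM, and Acta2 at 270, 1.89 and 3.39 CPM.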

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

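The tests of AT2 cells carried over in the lavage and all splits of the libraries were chosen only after the results were seen.

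The change from fresh cells to organoid differed between lavage and dissociated lung for 385 genes by the interaction test. Slc34a2 gained 3.84 ± 0.704 (log2, SE) more in lavage cells (adjusted p = 0.0191), Ndrg1 differed by -2.77 ± 0.618 (adjusted p = 0.0390) and Pla2g4c by -10.84 ± 2.39 (adjusted p = 0.0383). The fitted differences of Itln1 (-14.65 ± 2.89, adjusted p = 0.0252) and Ighm (17.10 ± 4.01, adjusted p = 0.0481) rest on at most 3 counts in BAL_3D and in BAL respectively, so their size is not determined. The starting mix also differed (AT2-like cells 5.22% in BAL, 17.3% in PD) and is not separated from a different response. As groups, AT2 and surfactant genes differed by a median of 1.72 (camera adjusted p = 2.20e-08; adjusted p = 0.194 with an estimated correlation), transitional epithelial genes by -1.62 (1.10e-06; 0.194), epithelial markers by -1.52 (4.60e-06; 0.194) and mesothelial markers by -4.11 (0.00412; 0.221). The fits of 3 against 3 libraries allow 10 splits, too few for a share under 0.05. The real splits gave 5717 genes in PD_3D against PD and 2896 in BAL_3D against BAL, where the highest other split gave 0 in each; 1 of 10 splits reached the real count. Replicate numbers pair PD_3D with PD, and the other 3 splits that part all 3 numbers gave 0 as well.

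AT2-like cells made up 76.1% of BAL_3D epithelial cells although the lavage held 12 of them. Over 16 AT2 and surfactant genes, the median level in AT2-like cells was 31.1 times that in macrophages of the same libraries. The ratio ran from 0.896 for Lpcat3 to 159 for Lamp3. AT2-like cells were named by markers of this kind, so a high ratio was set in large part by the naming. Free RNA of AT2 cells in the droplets is therefore not decided by it. AT2 cells carried over in the lavage stay open, since 5.22% of BAL epithelial cells were AT2-like. These AT2-like cells numbered 4, 2 and 6 in BAL 1, 2 and 3. Sftpc stood at 72.8, 6.84 and 2394 CPM in the epithelial sums of these libraries. In BAL 1 and BAL 2 the AT2 name therefore had little Sftpc behind it. No label traces an organoid cell to its source, so carry-over cannot be told apart from a change of airway cells. A change of club or ciliated cells towards AT2 may be part of it and was not tested.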

How the results depend on the processing

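The alternatives of AT2-like cells alone, Cell Ranger 8.0.1 libraries and 2 groups with a replicate block were chosen only after the results were seen. Over all alternatives, gene counts stayed within 1.5 times of the main count in 118 values, rose past it in 21 and fell below it in 39. Shares kept their direction in 237 values and turned in 2. Described lists kept their call in 84 values, lost it in 38 and turned in 1, and all 38 lost calls were with an estimated correlation. Of 165 named genes, 66 lost their call somewhere and 2 turned. For all changed values below the cause was not tested, unless the alternative tests fewer libraries or cells.

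Leaving out each library in turn gave 4621 to 6602 genes in epithelial PD_3D against PD, 2951 to 4032 in BAL_3D against BAL, 0 to 276 in BAL_3D against PD_3D, 0 to 114 in Mixed_3D against BAL_3D, 0 throughout in Mixed_3D against PD_3D (edgeR; 196 at an unadjusted p under 0.05) and 47 to 1148 in the interaction. In macrophages it gave 1828 to 2422 in BAL against PD, 2267 to 3234 in BAL_3D against BAL and 3 to 374 in Mixed_3D against BAL_3D. The lowest value in both epithelial comparisons between BAL_3D and another organoid came without BAL_3D 3, and in macrophages of Mixed_3D against BAL_3D without BAL_3D 1. The basal trend was -0.678 to 8.22 points, and within 8.0.1 the hillock trend was 1.36.

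In BAL_3D against PD_3D the count was 209 with DESeq2 size factors, 220 with no gene filter, 47 with the empty-barcode profile subtracted, 45 within 8.0.1, 205 at 10% mitochondrial UMIs, 1060 by DESeq2, 0 in a fit of the 2 groups and 220 in AT2-like cells. In Mixed_3D against BAL_3D it was 203 with no filter, 55 subtracted, 39 within 8.0.1, 208 at 2000 UMIs and 1000 genes, 188 at 10% mitochondrial UMIs, 821 by DESeq2, 0 in a fit of the 2 groups and 214 in AT2-like cells. In Mixed_3D against PD_3D it was 2 by DESeq2 and 2 in a paired fit of the 2 groups. In PD_3D against PD it was 3581 in AT2-like cells. The interaction gave 252 with no filter, 185 with the block, 145 subtracted and 149 within 8.0.1. In macrophages of BAL against PD it was 765 subtracted and 1643 within 8.0.1. In Mixed_3D against BAL_3D macrophages it was 255 with no filter, 30 with the block, 576 at 50 cells, 7 within 8.0.1, 292 at 10% mitochondrial UMIs, 679 by DESeq2 and 2 in a fit of the 2 groups.

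In AT2-like cells, Fasn was at -0.12 (adjusted p = 0.808) and Lamp3 at -1.23 (adjusted p = 0.00805) in PD_3D against PD, the reverse of all epithelial cells. Macrophage markers in Mixed_3D against PD_3D turned lower with the empty-barcode profile subtracted (adjusted p = 0.0132). The 4 untested comparisons have no value under any alternative, and the interaction has none by DESeq2 or in fits of 2 groups. In BAL the 1532040 epithelial UMIs limit what a count of 0 can show.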

Other observations

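The tests of tissue dissociation, of the ciliated list and the other 4 lists apart, and of all splits of the libraries were chosen only after the results were seen.

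In BAL_3D against BAL macrophages, 8 of 23 glycolysis and hypoxia genes rose and 2 fell (9 and 2 adjusted over the list alone; median 0.44, camera adjusted p = 0.00946; adjusted p = 0.494 with an estimated correlation), and 6 of 18 oxidative stress and glutathione genes rose and 3 fell (6 and 3 adjusted over the list alone; median 0.35, camera adjusted p = 0.0329; adjusted p = 0.164 with an estimated correlation). In Mixed_3D against BAL_3D macrophages, 2 of 15 TGF-beta target genes were higher (7 adjusted over the list alone; median 2.78, camera adjusted p = 1.84e-06; adjusted p = 0.107 with an estimated correlation), as were 3 of 18 transitional epithelial genes (5 adjusted over the list alone; median 1.25, camera adjusted p = 1.23e-06; adjusted p = 0.0242 with an estimated correlation).

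Epithelial cells of PD_3D had higher p53 and senescence genes than PD, 8 of 16 with 1 lower (8 and 1 adjusted over the list alone; median 1.07, camera adjusted p = 0.00203; adjusted p = 0.308 with an estimated correlation), and 6 of 13 genes of FGF and ERK feedback rose (7 adjusted over the list alone; median 1.14, camera adjusted p = 0.00706; adjusted p = 0.326 with an estimated correlation). In AT2-like cells 8 p53 and senescence genes rose and 1 fell (median 1.45, camera adjusted p = 0.00105, adjusted p = 0.328 with an estimated correlation), while 1 gene of FGF and ERK feedback rose and 2 fell (median -0.23, camera adjusted p = 0.666), so that rise was not found there. In BAL_3D against BAL, 8 of 19 transitional epithelial genes fell and none rose (8 adjusted over the list alone; median -0.42, camera adjusted p = 0.0367; adjusted p = 0.422 with an estimated correlation), and 3 of 10 basal genes rose (5 adjusted over the list alone; median 3.69, camera adjusted p = 0.0367; adjusted p = 0.574 with an estimated correlation).

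BAL macrophages had 2370 genes lower than PD macrophages. Free RNA of the dissociated lung may account for those of other cell types: 90.3% of their lower members stood under 50% of the empty-barcode level. Of all 2370 lower genes 62.7% did, at a median of 0.209 of that level. It is argued against for inflammatory genes, of which 12.5% did. Tissue dissociation stays open, with a median of -2.08 for its list, since no lavage cells went through dissociation, and so do the place in the lung and a different mix of macrophages and monocytes. The 10 splits of these libraries are too few for a share under 0.05 (3404 genes in the real one, 0 in the highest other).

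Between BAL_3D and PD_3D epithelial cells, camera called 14 lists and none with an estimated correlation. The 5 lists weighed here are the ciliated, extracellular matrix, chemokine, transitional and AT1 lists. A different mix of the named epithelial subtypes may account for the ciliated list, whose median in AT2-like cells was 0.416 of that over all epithelial cells. For the extracellular matrix, chemokine, transitional and AT1 lists the lowest ratio was 0.948. That argues against the numbers of named subtypes as the whole cause for them, and covers the named subtypes only. The median over all 5 lists was 0.999, which decides nothing for the lists together. Free RNA of other cells was not removed from the AT2-like sums, so a mix acting through it stays open. Mesothelial and neutrophil markers were lower in AT2-like cells as well (medians -4.84 and -2.41). AT2-like cells of the 2 groups lay in largely separate subclusters, the largest holding 2485 PD_3D and 117 BAL_3D cells and the next 33 and 1994, so a different mix within AT2-like cells stays open. The Cell Ranger version is argued against, since the medians within 8.0.1 were 0.808 of those in all libraries, with a lowest of 0.757. The cells seeded stay open as the biological difference, and as a hypothesis only.

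For the other comparisons the 10 splits of 3 against 3 libraries are likewise too few for a share under 0.05. The real split of a 2-group fit gave 0 genes and the highest other 1 in BAL_3D against PD_3D, 0 and 17 in Mixed_3D against PD_3D, and 0 and 0 in Mixed_3D against BAL_3D (edgeR). A real count of 0 is reached by all 10 of 10 splits whatever the data, so these splits decide nothing. The split with 17 genes kept replicates 1 and replicates 2 of Mixed_3D and PD_3D together, with both 7.1.0 libraries on one side. The split of PD_3D 1, PD_3D 2 and Mixed_3D 1 from the rest also put both on one side and gave 0 genes. A structure by replicate number or by version is therefore not shown by the split with 17 genes. The 4 splits that part all 3 replicate numbers, the real one among them, gave 0 genes each, and this comparison within 8.0.1 gave 0. In macrophages it gave 3612 and 0 in BAL_3D against BAL and 2 and 1 in Mixed_3D against BAL_3D, with 1 of 10 splits each.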
